A study of Capra hircus with 6 samples.

How the data were processed

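Lactating mammary gland of 6 goats was profiled on 6 spotted oligonucleotide arrays with 2 colours. The goats carried either the Low or the High genotype at CSN1S1, the gene of alpha-s1-casein, a main milk protein, and were fed a control diet without restriction, per the labels. Each array received the RNA of 1 Low and 1 High goat. The labels name 3 independent comparisons, so there were 3 pairs of goats, and each pair was hybridised to 2 arrays with the dyes swapped. Per the labels, 5 ug of total RNA was labelled directly with Cy5 or Cy3 for each channel. The replicate in every test was the pair (n = 3), and the 2 arrays of a pair counted as 1 replicate.

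The deposited scanner files held 1 channel each (12 files). Per the file headers and the labels, the authors measured the intensity of every spot and of its local background with ImaGene 6.0, as means over pixels. The deposited background SD was a signal in the same pixel units, per the file headers. The deposited series values were log2 ratios of Low over High per spot, and their software and normalization are not given in the sources used here. Over spots with a mean log2 signal above 10, these deposited log2 values correlated with the scanner ratios at r between 0.967 and 0.996 across spots, with slopes between 0.941 and 0.991. Moved by 1 sub-grid, the same values gave r between 0.0437 and 0.193, so row number was taken as the match between tables. The medians of the 6 deposited columns were 0.0205, -0.0135, 0.0186, -0.0076, 0.0038 and -0.0094. The scale (log2) and direction (Low over High) of these columns were thereby settled, while how they were centred stays unknown. The dye named in the header matched the label in 12 of 12 files. No per-sample column was left unmapped.

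Each array held 19200 spots in sub-grids of 400: 8379 probes with 2 spots each, 1536 spots named empty and 906 named blank. Probes were designed for cattle, and their names came from an old platform annotation with cattle identifiers. Of the probes, 6840 had 1 gene symbol, 93 had several and 1446 had none. Of the 6535 single symbols, 6019 (92.1%) occur in the goat gene table of assembly ARS1.2, which was used only for names and gene order. No genome build is given in the sources used here, so no coordinates are printed. A probe with several symbols was not named, which leaves CSN2 (beta-casein) not analysed here. How well a cattle probe binds its goat transcript is not known here, nor whether the CSN1S1 probe lies in a part of the transcript that the alleles alter.

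Background means were corrected with normexp (offset 50) and ratios were normalized by global loess within each array in limma 3.58.1 (R 4.3.3, statmod 1.5.0), with control spots at weight 0. Spots flagged as manual or empty were set to missing. The software's flag for poor spots fell on 16 spots, all 16 of them marked saturated, and these were kept because the design excluded saturation from the flags to remove. A first fit had set them to missing, and this was changed after its result (CSN1S1 at -2.37) was seen; that version is given among the alternatives. Ratios were turned to Low over High by the dyes in the labels, duplicate spots were averaged, and then the 2 arrays of a pair. A probe was kept when its signal exceeded the background mean plus 2 background SDs in the Low or in the High channel on at least 1 array of each pair, which left 6378 probes (5066 named genes). Low over High was tested against 0 with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all probes kept and a threshold of 0.05. A gene with several probes was represented in lists by the probe with the highest mean intensity. Intervals are at 95% and come from the same moderated fit. An exact sign-flip permutation over 3 pairs cannot give a two-sided p below 0.25.

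Gene lists (25) were written before the data were examined, and the 24 with at least 5 measured genes were tested with limma's camera at its preset correlation of 0.01, beside camera with an estimated correlation and fry. Named genes followed a rule fixed at the same time. It takes CSN1S1 and all measured milk proteins, then up to 12 falls and 12 rises past the threshold with 1 sign on all 6 arrays. Places left over are filled by unadjusted p, and such genes are described as not past the threshold. It adds 3 members of each list that passed and the most intense marker of each cell type list. A sentence says so where a gene outside this rule is named.

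The steps were tested on simulated data: 20 sets of 6378 probes with the probes' own moderated spread and dye effects. In each, 50 probes were changed at each of 4 sizes, and 94.6% of those changed by 1.25-fold and 100% of those changed by 1.5-fold or more were called. On average 7.61% of calls were false, and with no change simulated a mean of 1.2 probes was called. A list of 20 genes shifted by 0.15 was found in 100% of simulations. The myoepithelial list, called in the data, was shorter and less shifted (7 genes, mean 0.0903), and recovery at that size was not simulated. The simulation drew independent probes, so it leaves out correlation between genes. The shares recovered are optimistic, because the moderated spread is smoother than the raw one. They also rest on 200 changed probes per set, which eases the Benjamini-Hochberg threshold, against 7 probes called in the data. In the data GPX2, at 1.64-fold, was not called (limma adjusted p = 0.149). The simulated dye effect was equal in all pairs and cancels in the pair mean, so the simulation does not test its removal.

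Alternatives were background correction, normalization, filters, flags, the unit of replication, single dye orientations, the variance model, multiple testing, the deposited values and leaving out each pair. Alternatives added after seeing the data were the removal of saturated spots, the removal of 3 probes near CSN1S1, gene lists without CSN1S1, and the day of image quantification. The files give 2 such days: both arrays of pair 1 and 1 of pair 3 belong to one day, the others to the second. Both genotypes lie on every array and therefore on both days. Dye orientation is not balanced within a day. Each day alone holds 1 array of pair 3 without its dye swap, so the dye effect of that pair stays in the ratio. For fits over 6 arrays and for the trend and robust fit, lists were tested with cameraPR on the moderated statistics.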

Results

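The mammary transcriptome of lactating goats with a Low and with a High genotype at CSN1S1 was compared on 6 arrays, made from 3 pairs of goats with a dye swap for each pair. The comparison asks how this milk protein polymorphism affects gene expression in the gland. All ratios are Low over High on the log2 scale, so a negative value means lower in Low. Between 74.1% and 82.2% of probe spots per array were neither manually flagged nor flagged as empty. The Cy3 channel had the higher background on all 6 arrays. The number of arrays limits the precision, and the median standard error of a probe was 0.049.

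CSN1S1, which encodes alpha-s1-casein, was the most strongly changed gene. Its ratio (probe Bt00006833) was -2.43 ± 0.22 (SD, n = 3 pairs; 95% interval -2.63 to -2.22), so its level in Low was 18.6% of that in High, or 5.37 times lower. The ratio was -2.63 in pair 1, -2.20 in pair 2 and -2.44 in pair 3, and was negative on 6 of 6 arrays, from -2.73 to -1.92 (limma adjusted p = 5.13e-04). The Low goats still gave a strong signal, at a mean of 7350 units above background against 39300 in High. At least 1 High spot was saturated on 1 array each of pairs 2 and 3, where the measured difference is a lower limit of its size. The exact sign-flip permutation over 3 pairs gave p = 0.25, the smallest it can give.

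No other milk protein gene passed over all probes. Of the 9 measured genes of this list, 1 fell (CSN1S1), 0 rose and 8 did not pass adjusted over all probes, while 2 fell adjusted over the list alone, namely CSN1S1 and PAEP. PAEP, the gene of beta-lactoglobulin, had a ratio of -0.26 ± 0.11 (SD, n = 3 pairs) and a limma adjusted p of 0.424 over all probes and 0.014 over the list alone. PAEP was lower on 4 of 6 arrays. Its ratio was -0.63 on the 3 arrays with Low in Cy5 alone and 0.11 on the 3 with Low in Cy3 alone, where dye effects stay in the ratio. CSN1S2 (alpha-s2-casein) was at -0.07 ± 0.17, or -0.037 without its 1 saturated spot, and LALBA (alpha-lactalbumin, part of lactose synthase) at -0.19 ± 0.29. The 2 probes of CSN3 (kappa-casein) gave 0.19 ± 0.44 (1 saturated spot) and 0.10 ± 0.38. GLYCAM1 (a mucin-like milk protein) was at -0.07 ± 0.24, LPO (lactoperoxidase) at 0.13 ± 0.19, and PIGR (the polymeric immunoglobulin receptor) at -0.02 ± 0.08. LTF (lactoferrin, an iron-binding defence protein) varied most between pairs, at 1.07, 0.29 and -0.30. The camera test of the list gave a downward adjusted p of 0.159, and of 0.74 with an estimated correlation. PAEP, LALBA, CSN1S2 and LTF each passed over all probes in 1 of 20 alternatives.

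Beyond CSN1S1, few genes could be called different between the genotypes with 3 pairs. Of 6378 probes, 7 passed and all 7 were lower in Low, with 0 higher, while 342 had an unadjusted limma p below 0.05 (177 lower, 165 higher; 319 expected by chance). LAPTM4A, which encodes a membrane protein of lysosomes and late endosomes, was at -1.53 ± 0.26 (SD, n = 3 pairs), or 2.89 times lower in Low (adjusted p = 0.00897). LRPPRC, which binds and stabilises mitochondrial mRNA, was at -0.90 ± 0.20 (adjusted p = 0.0289), and its probe number directly follows that of CSN1S1. GNPTAB, which encodes part of the enzyme that starts the mannose-6-phosphate tag of lysosomal enzymes, was at -0.61 ± 0.10 (adjusted p = 0.0289). CYB5R3, an NADH-cytochrome b5 reductase, was at -0.66 ± 0.15 (adjusted p = 0.0408), and its spots lie next but one to those of CSN1S1. TFDP2, a partner of the E2F cell cycle transcription factors, was at -0.50 ± 0.04 (adjusted p = 0.0289), and the unnamed probe Bt00000700 at -0.47 ± 0.04 (adjusted p = 0.0359). The 6 named genes were lower on 6 of 6 arrays and Bt00000700 on 5 of 6. In the Low channel, CYB5R3 exceeded background on 3 of 6 arrays, LAPTM4A and TFDP2 on 4 and LRPPRC on 5. With the background subtracted, the ratios were -2.18 for LAPTM4A (4.55 times lower in Low), -1.83 for CYB5R3, -1.55 for LRPPRC and -1.07 for TFDP2. In that setting CYB5R3 (limma adjusted p = 0.18), TFDP2 (0.17), GNPTAB (0.18) and Bt00000700 (0.17) did not pass, while LAPTM4A and LRPPRC did (0.0356). With background medians the ratios were smaller in size, at -1.38 for LAPTM4A, -0.51 for CYB5R3, -0.78 for LRPPRC and -0.40 for TFDP2. Without the probes of CSK, CYB5R3 and LRPPRC, which lie near CSN1S1 on the array or in probe number, the count was 5. This removal takes out the calls of CYB5R3 and LRPPRC themselves, so it does not test the other calls. The count was 1 with a trended, robust variance and 0 without moderation of the variance (CSN1S1 included, with 2 degrees of freedom). It was 32 with the pair as a random block over 6 arrays, in a fit without a dye term and not on pair means. Leaving out pair 2 left 2 calls, CSN1S1 and LAPTM4A, and leaving out pair 3 gave 32 (23 lower, 9 higher).

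**Figure D1:**
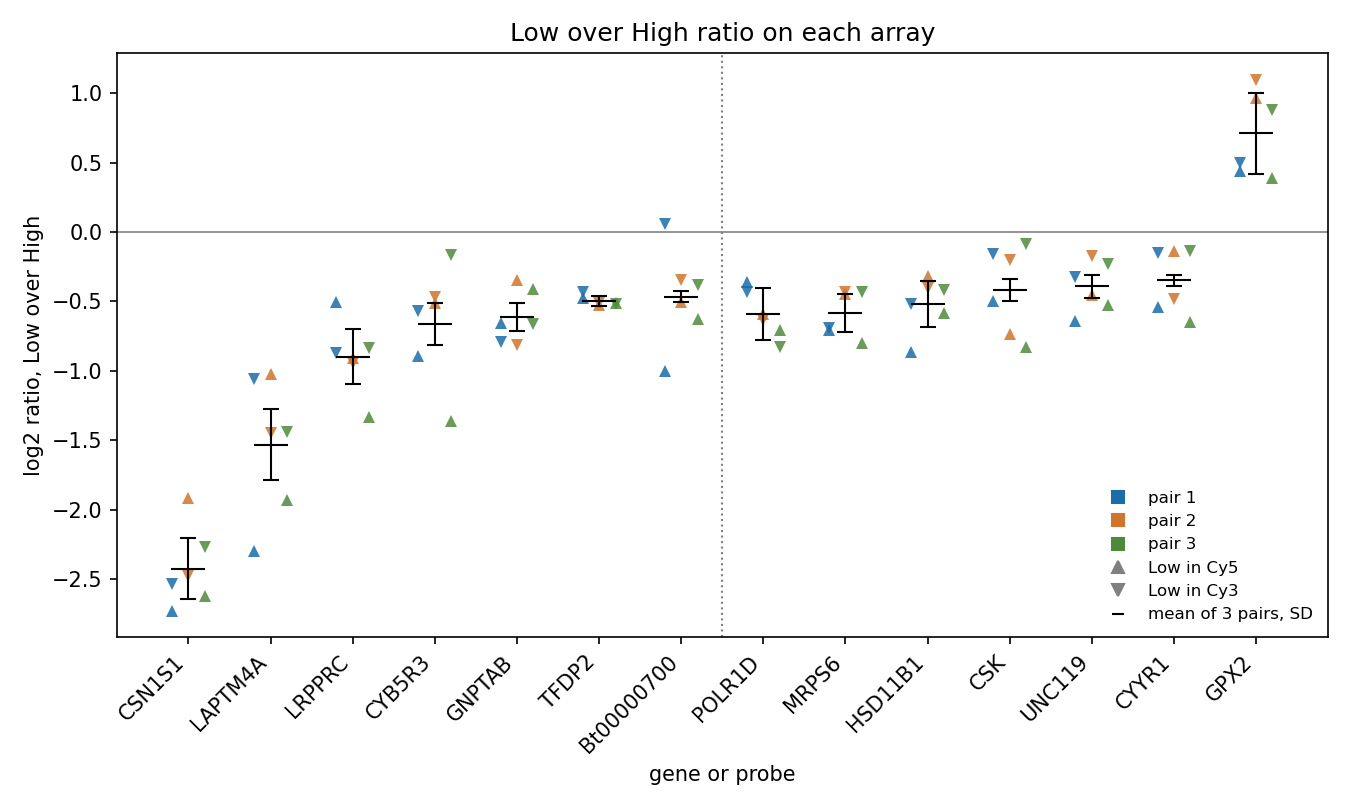
Log2 ratio of Low over High (vertical axis) on each of the 6 arrays for the 7 probes past the threshold (left of the dotted line) and for 7 that did not pass (right), by goat pair (colour) and dye of the Low sample (triangle up Cy5, triangle down Cy3); bars give the mean and SD of 3 pairs. CSN1S1 lies between -2.73 and -1.92 on the 6 arrays, LAPTM4A between -2.30 and -1.02, and GPX2 above 0 on all 6.

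Next in order came 6 further genes that were lower in Low on 6 of 6 arrays but did not pass the adjusted threshold. MRPS6, a protein of the mitochondrial ribosome, was at -0.58 ± 0.13 (SD, n = 3 pairs; limma adjusted p = 0.051). CSK, a kinase that restrains Src family kinases, was at -0.42 ± 0.08 (adjusted p = 0.0701), and its spots lie directly beside those of CSN1S1. One probe of POLR1D, a subunit of RNA polymerases I and III, was at -0.59 ± 0.19, but the brighter probe of the gene was at 0.04 ± 0.11. HSD11B1, which regenerates active glucocorticoid, was at -0.52 ± 0.16, UNC119, which traffics lipid-modified proteins, at -0.39 ± 0.08 and CYYR1 at -0.35 ± 0.04. In the Low channel CYYR1 and the lower probe of POLR1D exceeded background on 4 of 6 arrays. Over 20 alternatives this POLR1D probe ranged from -1.025 to -0.50, HSD11B1 from -0.85 to -0.43 and CYYR1 from -0.73 to -0.24. In the other direction no probe passed. The 12 genes named here are those with the lowest unadjusted p among named genes higher in Low on 6 of 6 arrays, out of 30 such probes, with or without a name, at an unadjusted limma p below 0.05. GPX2, a glutathione peroxidase, had the largest of these ratios at 0.71 ± 0.29 (adjusted p = 0.149), or 1.64 times higher in Low. KCNH3 (a potassium channel) followed at 0.46 ± 0.30. The remaining 10 lay between 0.14 and 0.28: PSMB6 (a proteasome subunit), EIF4A3 (of the exon junction complex), CD9 (a tetraspanin), HSPA5 (the endoplasmic reticulum chaperone BiP), BNIP1, PCNP, BCL2L12, OARD1, MTMR11 and KIAA1191. HSPA5 and BNIP1 exceeded background in the High channel on 3 of 6 arrays and MTMR11 on 2. Over 20 alternatives MTMR11 ranged from 0.079 to 0.72, HSPA5 from 0.091 to 0.55, BNIP1 from 0.13 to 0.53 and CD9 from 0.15 to 0.46. The second, dimmer probe of EIF4A3 was at 0.05 ± 0.13. For MTMR11 the named probe is the dimmer one, and the brighter probe of the gene was at 0.09 ± 0.11.

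In the main fit, no list of milk fat, protein export or translation genes shifted as a group. Of the 22 measured genes of fatty acid and triacylglycerol synthesis, 0 rose, 0 fell and 22 did not pass (median -0.0034). Adjusted over the list alone, 1 fell: GPAM, which catalyses the first step of triacylglycerol synthesis, at -0.44 ± 0.16 and lower on 6 of 6 arrays. FASN, the fatty acid synthase, was at -0.33 ± 0.28. GPAM, FASN and RPL22 were chosen after their values were seen. Genes of the milk fat globule (9 measured, median -0.0044), sterol synthesis (10, 0.01) and glucose and lactose supply (8, 0.03) had 0 calls. The 24 endoplasmic reticulum chaperone and stress genes had a median of 0.02 and 0 calls, with HSPA5 at 0.20 ± 0.10. The 34 secretory pathway genes had a median of 0.02 and 0 calls. Of 38 ribosomal protein genes, 24 were above and 14 below 0 (median 0.02), 0 passed, and adjusted over the list alone 1 fell, RPL22 at -0.50 ± 0.19. Translation factors (26, median -0.0084), the respiratory chain (42, -0.0066), the proteasome and ubiquitin (32, 0.01) and amino acid supply (8, 0.04) had 0 calls, adjusted over all probes or over the list alone. So did hormone signalling (15, -0.02), ion transport (7, 0.0032), cytosolic stress (14, 0.01), cell death and involution (17, -0.03) and proliferation (18, -0.0018). For milk fat globule, sterol synthesis, lactose supply, translation factor, proliferation and fibroblast genes, the mean and the median of the list differed in sign. The camera adjusted p of these lists lay at or above 0.462.

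Among the lists of cell type markers, 1 shifted by camera. The 7 measured genes of myoepithelial and smooth muscle cells, which contract to eject milk, were all above 0, with a mean of 0.09 and a median of 0.04, and camera gave an upward adjusted p of 0.0335. The call is lost with an estimated correlation (adjusted p = 0.74) and with fry (adjusted p = 0.215). Of its members, 0 passed over all probes and 1 rose adjusted over the list alone, KRT17, a basal keratin, at 0.23 ± 0.09 (SD, n = 3 pairs). MYLK, the myosin light chain kinase, was at 0.20 ± 0.13 and CNN1, a smooth muscle calponin, at 0.08 ± 0.04, with its second probe at -0.05 ± 0.03. ACTA2, smooth muscle actin and the most intense marker, was at 0.02 ± 0.14. KRT17 turned to -0.0062 on the 3 arrays with Low in Cy5 alone, CNN1 and ACTA2 turned negative on the 3 with Low in Cy3 alone, and ACTA2 also under median centring. The call was absent without background correction (list mean 0.0854), under median centring (0.0783), with the deposited values (0.0752) and without pair 1 (0.077) or pair 2 (0.0896), against a list mean of 0.0903.

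In the main fit the other cell type lists had 0 calls, adjusted over all probes or over the list alone, and no camera call. Luminal epithelial markers (9 measured, 7 above 0) had a median of 0.04, with the tight junction gene CLDN4 at 0.05 ± 0.07 and at -0.00030 over the 3 arrays with Low in Cy3. Endothelial markers (6, all 6 above 0) had a median of 0.04, with COL4A1, a basement membrane collagen, at 0.04 ± 0.08. Fibroblast markers (7, of which 4 above 0) had a median of 0.0025, with DCN, the matrix proteoglycan decorin, at -0.05 ± 0.04. Adipocyte markers (9, of which 3 above 0) had a median of -0.0067, with PCK1, of gluconeogenesis, at -0.01 ± 0.04 and its second probe at -0.14 ± 0.24. Leukocyte markers (22, of which 10 above 0) had a median of -0.01, with BOLA-DMA, of antigen presentation, at 0.08 ± 0.14. Skeletal muscle markers (7, of which 1 above 0) had a median of -0.02, with MYH1, a myosin heavy chain, at 0.04 ± 0.11. Of the red blood cell markers 2 were measured, too few to test, with ALAS2, of haem synthesis, at -0.04 ± 0.06.

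**Figure D2:**
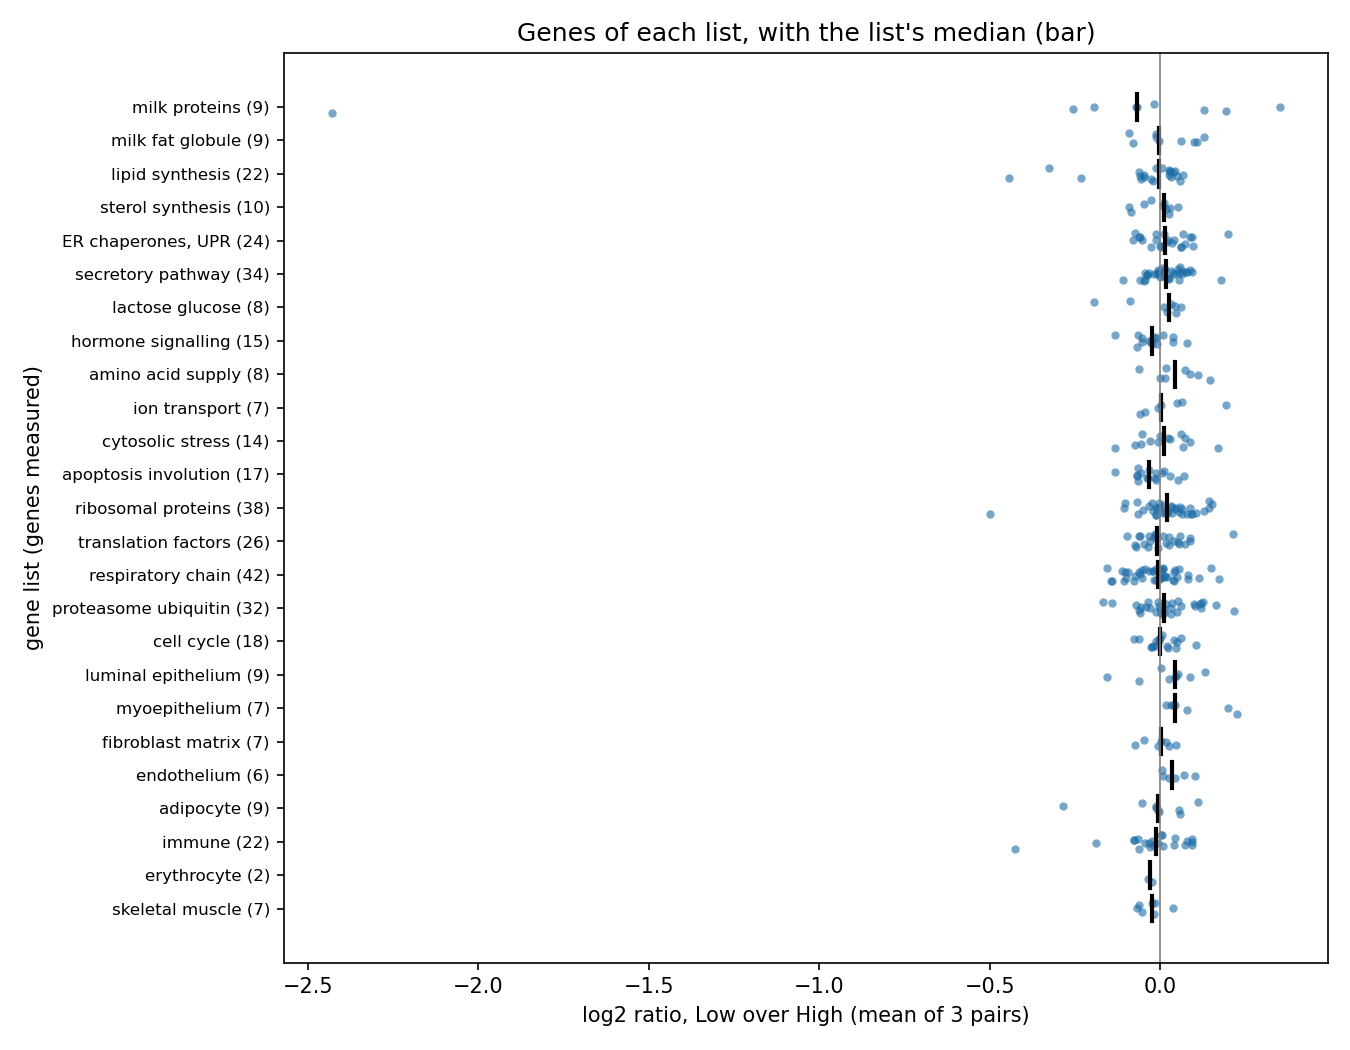
Log2 ratio of Low over High (horizontal axis, mean of 3 pairs) of each measured gene (points) in the 25 gene lists (vertical axis, number measured in brackets), with the median of each list as a bar. CSN1S1 at -2.43 stands apart, and the list medians lie between -0.07 and 0.04.

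The 3 goat pairs shared the CSN1S1 difference and agreed little over the probes as a whole. Across probes, which are not independent replicates, the pair ratios correlated at r = 0.152 (pairs 1 and 2), 0.271 (1 and 3) and 0.0352 (2 and 3), with rho of -0.0260, 0.213 and -0.0657. The sign was shared by all 3 pairs for 26.8% of probes, against 25% by chance. Before averaging, the 2 arrays of a pair correlated negatively after turning for dye, at r = -0.239, -0.430 and -0.435, with an SD of their difference of 0.318, 0.367 and 0.445. The median absolute dye effect of a probe was 0.0952, 0.108 and 0.141 in the 3 pairs, larger than the median absolute ratio of Low over High at 0.0624, 0.0557 and 0.0725. Averaged over the 3 pairs, CSN1S1 was at -2.42 with Low in Cy5 and at -2.43 with Low in Cy3. Within pair 1 the 2 orientations gave -2.73 and -2.54, in the same order. They gave -1.92 and -2.48 in pair 2, and -2.62 and -2.27 in pair 3. The saturated High spots of CSN1S1 lay on the arrays of pairs 2 and 3 with Low in Cy5.

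**Figure D3:**
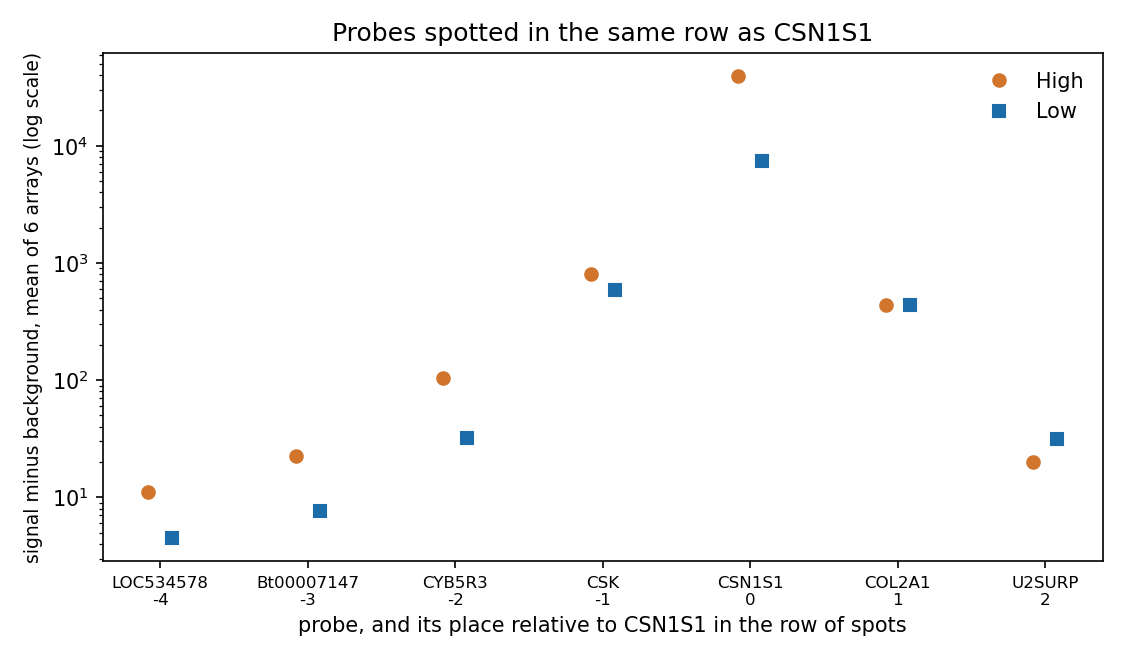
Signal minus background (vertical axis, log scale, mean of 6 arrays) of the probes spotted in the row of CSN1S1 (horizontal axis, place relative to CSN1S1) in High (circles) and Low (squares). CSK and CYB5R3 on one side were lower in Low, with 586 against 804 and 31.9 against 105 units. COL2A1 on the other side, outside the rule for named genes and shown for its place, had 438 against 439.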

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

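The tests on CSK, CYB5R3, LRPPRC and the dyes were chosen after the results were seen, and the count under a floor replaced a first test on CSK that had shown no difference; the sign flips were planned. Among 51 sets of 6 array values, 3 held an array far from the other 5, and chance gives about 1 in 20. On the array of pair 3 with Low in Cy5, 82.2% of probe spots were unflagged against 74.1% to 76.5% on the others. The same array had 5392 spots flagged empty against 6321 to 6730. On the array of pair 3 with Low in Cy3, duplicate spots correlated at 0.551, against 0.741 to 0.80.

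Outside the probes, 4 of 2442 control spots were above background and unflagged on at least 4 of 6 arrays. These are 2 duplicate pairs of blank spots, 1 pair next to each of the very bright probes PAEP and Bt00008263, on the side where CSK and CYB5R3 lie from CSN1S1. In each pair 1 spot touches the bright probe and the other lies 1 spot further, with net signals of 131 and 276 beside PAEP and of 139 and 65.2 beside Bt00008263. The mean blank signals there were 0.686% and 1.05% of the bright probe's, and 0.0721% to 0.144% next but one. With the median blank level removed they were 0.647% and 0.929%, and 0.0256% to 0.0613% next but one.

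This bears on the lower ratios of CSK and CYB5R3. The High minus Low difference at CSK was 0.684% of that at CSN1S1, within the 0.647% and 0.929% of the 2 groups of blank spots, of which 1 reaches it, so carry-over of CSN1S1 probe by the spotting pin may account for it. At CYB5R3 the difference was 0.228%, above the 0.0613% reached next but one at the 4 groups of blank spots, while 1 blank a place further reached 0.0869%. Beyond CYB5R3 the difference was 0.0464% and 0.0205% at the next 2 probes, which did not pass the background filter. Their net signals, 4.49 to 22.4 units, lie around the median blank level of 11.6, so no fall-off can be read from them. Next but one on the other side of CSN1S1, a probe that also did not pass was at -0.0355%. Over 49 bright probes the place next but one was brighter on the side of CYB5R3 than on the other, by a median log2 of 0.926 (permutation p = 0.107). Directly beside other bright probes, neither test showed carry-over in general. In the first, neighbours on that side differed from those on the other by a median log2 of -0.746 (62 compared, permutation p = 0.654). In the second, 13 of 66 neighbours on that side lay under a floor of 0.343% of the bright signal, against 18 of 72 on the other side (Fisher's exact p = 0.542). For CSK and CYB5R3 carry-over and lower transcript levels in Low cannot be told apart, since the array holds 0 other probes of either gene to test lower transcript levels. For LRPPRC, mixing of neighbouring wells was tested on other bright probes, where the next-numbered probe differed from the previous one by a median log2 of -0.403 (permutation p = 0.208). This leaves a single mixed well open, so that for LRPPRC mixing and a lower transcript level cannot be told apart.

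The arrays of a pair disagreed over most probes. Arrays of different pairs, which share no goat, also correlated at a mean r of -0.429 when their dye orientation was opposite and at 0.561 when it was the same, as a probe-specific dye effect would give. Wrongly named dyes on 1 array of each pair are argued against by CSN1S1, whose highest ratio on the 6 arrays was -1.92. No biological explanation was tested for this pattern.

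For the count of 7 probes, the 3 pairs allow 4 sign flips, too few for a share under 0.05. The real signs gave 7 probes in 1 of 4, and the highest of the other flips gave 0.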

How the results depend on the processing

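The alternatives on saturated spots, probes near CSN1S1, the day of quantification and lists without CSN1S1 were chosen after the data were seen. CSN1S1 kept its direction and passed under the 20 alternatives tallied for it, from -2.54 to -2.32 (highest limma adjusted p among these = 0.0356). That tally leaves out changes of the filter, the variance model and multiple testing, and the removal of probes near CSN1S1. The ratio of CSN1S1 was -2.45 and -2.41 within the first and second day and -2.43 with the day as a term. Setting saturated spots to missing gave -2.37. Over all 27 settings CSN1S1 was called in 26, and not without moderation of the variance, with 2 degrees of freedom. Of 27 settings, LAPTM4A was called in 25 and GNPTAB and Bt00000700 in 15. Of the 26 that tested their probes, LRPPRC was called in 21, TFDP2 in 16 and CYB5R3 in 12. The cause of the lost calls was not tested. These tallies overstate stability, since unadjusted p cannot lose a call. They also include single orientations, where dye effects stay in the ratio, and a fit that takes the 6 arrays as independent. With the background setting the ratios moved by over 1.5 times: CYB5R3 (above background on 3 of 6 Low arrays) from -0.51 to -1.83, TFDP2 from -0.40 to -1.07, LRPPRC from -0.78 to -1.55, LAPTM4A from -1.38 to -2.18, GNPTAB from -0.58 to -0.91 and Bt00000700 from -0.40 to -0.63.

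The count of 7 probes stayed within 1.5 times in 10 alternatives and moved in 17. Among the 10 is the removal of CSK, CYB5R3 and LRPPRC, which takes out calls by itself. The count was 4 without background correction, 3 with the background subtracted, 2 with an offset of 0 and 12 with signal above background on all 6 arrays, where fewer probes were tested. Over 6 arrays it was 32 with the pair as a random block and no dye term (31 lower). It was 33 with a dye coefficient and no block (28 lower, 5 higher). It was 1025 (530 lower, 495 higher) with Low in Cy5 only and 484 (267 lower, 217 higher) with Low in Cy3 only, where dye effects stay in the ratio. It was 1 with trend and robust, 2 by Bonferroni, 342 at unadjusted p, 0 without moderation, 29 with the day as a term, 37 on the first day only (21 lower, 16 higher) and 3 on the second. Each day alone holds 1 array of pair 3, so the dye effect of that pair stays in the ratio. Leaving out 1 replicate gave 2 to 32: 3 of the 7 calls remained without replicate 1, 2 without replicate 2 and 7 without replicate 3 (23 lower and 9 higher in all). The cause was not tested for the other changes.

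The 1 list shift became 0 without background correction, with the background subtracted, an offset of 0, median centring, flagged spots kept, the pair as a random block, Low in Cy3 only, trend and robust, the deposited values, the day as a term, an estimated correlation and fry; the cause was not tested. The mean of this list, 0.0903, kept its sign in every setting and was 0.0854, 0.135, 0.107, 0.0783 and 0.0851 in the first 5 of these, 0.098 with Low in Cy3 only, 0.0752 with the deposited values and lowest on the second day (0.06). Leaving out 1 replicate gave 0 to 1. With Low in Cy5 only, without replicate 2 and on each day alone, 1 other list was called, downward. The camera adjusted p was 0.0017 with Low in Cy5 only and 0.0016 without replicate 2. It was 0.00424 on the first day and 6.48e-05 on the second, all lower than the 0.0335 of the main call. The list is not named here, and whether it was the same in each setting is not given. The mean correlation of the 2 arrays of a pair was -0.223 under print-tip loess against -0.368.

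Of 880 values of named genes, 740 were the same, 61 gained and 37 lost a call, and 42 changed sign, all among genes not called; the cause was not tested. With Low in Cy3 only these were CSN1S2 0.22, GLYCAM1 0.060, LALBA 0.15, PAEP 0.11, PIGR 0.16, CNN1 -0.19, CLDN4 -0.00030, ACTA2 -0.20, DCN 0.087, PCK1 0.19, BOLA-DMA -0.019 and ALAS2 0.17. With Low in Cy5 only they were CSN3 (1001864570) -0.17, CSN3 (Bt00006553) -0.26, LPO -0.10, LTF -0.029 and KRT17 -0.0062. Print-tip loess gave PIGR 0.015 and median centring ACTA2 -0.0011. The first day gave PAEP 0.0064, PIGR 0.046, CNN1 -0.085, ACTA2 -0.072, DCN 0.037, PCK1 0.078, ALAS2 0.042 and MYH1 -0.059. The second day gave CSN3 (Bt00006553) -0.074, LTF -0.20 and COL4A1 -0.047. Leaving out 1 replicate gave CSN1S2 -0.16 to 0.0067, CSN3 (1001864570) -0.063 to 0.32, CSN3 (Bt00006553) -0.11 to 0.25, GLYCAM1 -0.20 to 0.042, LTF -0.0057 to 0.68, PIGR -0.060 to 0.018, ACTA2 -0.023 to 0.10, COL4A1 -0.00051 to 0.071, PCK1 -0.037 to 0.0020, BOLA-DMA -0.0046 to 0.12 and MYH1 -0.016 to 0.092.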

Other observations

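The test of gene order was chosen before its result was seen, and its repeats and the mixed test without CSN1S1 after. In fry's mixed test, which takes changes in either direction, 3 lists passed: milk proteins (adjusted p = 0.0212), translation factors (0.0212) and myoepithelial markers (0.0045). Without CSN1S1 the milk proteins no longer passed (0.727), while the others stayed at 0.0244 and 0.0045. Of the translation factors 0 passed singly, over all probes or over the list alone. EIF4A3 had the largest ratio among them at 0.21 ± 0.05 (SD, n = 3 pairs), with 0.05 on its second probe. Among genes chosen after their values were seen, JCHAIN, the joining chain of secreted antibodies, was at -0.43 ± 0.63, and LEP, the adipocyte hormone leptin, at -0.29 ± 0.21 on one probe and 0.0055 on the other.

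Goats with unlike CSN1S1 alleles may also differ in DNA around the gene, and expression of genes linked to CSN1S1 might then differ more than that of others. Among the 100 genes on either side of CSN1S1 in the goat gene order, 22 probes were measured, 14 lower and 8 higher in Low. Their median absolute log2 ratio was 0.0716 against 0.0400 for 4808 other probes, a difference of 0.0316 (one-sided permutation p = 0.00457). The permutation shuffled probes, which come from the same 3 goat pairs and are not independent, so its p does not measure variation between goats. Both probes of CSN3 are among the 22. Without 3 milk protein probes the difference was 0.0252 (19 probes, permutation p = 0.0268). Against the 100 probes nearest in intensity, these 19 had a median percentile of 76, and 13 of the 19 lay above 50. JCHAIN, at -0.43, had the largest ratio in size among the 22. The lowest unadjusted limma p among the 22 belonged to ANXA3, an annexin outside the rule for named genes, at -0.15 (adjusted p = 0.849). Of the 22, 0 passed. The pattern is small and a hypothesis only, since larger spread between goats in this region would look alike.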
